A study of Homo sapiens with 8 samples.

How the data were processed

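RNA was sequenced from MHCC-97H, a human hepatocellular carcinoma cell line, after 24 hours with DMSO, the drug's solvent, or with lenvatinib, an inhibitor of the VEGF and FGF receptor kinases and of PDGFRA, KIT and RET. There are 4 DMSO libraries and 1 lenvatinib library at each of 40, 60, 80 and 100 µM. The labels do not say whether the DMSO libraries come from separate cultures, so the p-values given here measure only the spread between these libraries, which may be technical. Library preparation and strandedness are not given in the sources used here.

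Per the file headers, the deposited table holds read counts, TPM and FPKM for 20263 genes with Ensembl identifiers and symbols. The submitters' processing notes name FastQC, HISAT2, bedtools and StringTie and the GRCh38 genome build; their versions and the upstream gene annotation release are not given in the sources used here. The counts deposited by the authors are whole numbers, and each library's deposited TPM is a constant multiple of its FPKM within rounding. Only the counts were analysed. They sum to between 10181973 and 37384578 per library, so 3 counts, the upper limit that a count of 0 allows, correspond to between 0.0802 and 0.295 CPM (counts scaled to the library total). These limits cover counting error only. Of the genes, 4675 had no read in any library.

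The 11827 genes with a mean of at least 1 CPM over the 8 libraries were tested, and they hold 99.9% of all counts. The 4 lenvatinib libraries were compared with the 4 DMSO libraries with edgeR 4.0.16 under R 4.3.3 (TMM scaling, robust quasi-likelihood fit, 6 residual degrees of freedom). Differences between doses count as spread in this fit. A dose slope was tested as the log2 change per 20 µM within the lenvatinib arm, centred at 70 µM, with the arm as a second term. Each dose was also set against DMSO in a fit with 5 groups, where the lone library is assumed to vary as the DMSO libraries do (3 residual degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values in the text are TMM-scaled, with the SD over the 4 libraries of an arm. Gene positions are those of GENCODE v29 on GRCh38, matched by Ensembl identifier.

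Of 40 gene lists, 37 had at least 3 tested members and entered camera of limma 3.58.1 with a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, and fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, was run beside it. Adjusted p-values of lists are over these lists. Calls are also counted with p-values adjusted over the list alone.

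The comparisons, tests, thresholds, gene lists, a first set of alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 highest and the 12 lowest log2 fold changes among called genes whose 4 lenvatinib libraries all lie outside the DMSO range on the same side, with a symbol and a mean of at least 5 CPM in the higher arm. It takes up to 6 called genes on each side of the dose slope with a mean of at least 5 CPM over the lenvatinib libraries, and up to 4 members with the smallest adjusted p of each list described. KDR, FGFR1, FGFR2, FGFR3, FGFR4, FGF19, DUSP6, CDKN1A, MKI67, ATF4, DDIT3, ASNS, HMGCS1, ALB, AFP and EGFR are named in any case, and genes under the filter are given as their level. Of the genes these rules name, 2 are not reported here.

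After the data had been seen, a trend with GC content was found between the libraries, and fits that take it into account were added. GC content and length are those of the longest GENCODE v29 transcript of each gene (4 of the tested genes had none). Each library's GC slope is the slope of its log2 deviation from the mean of the 8 libraries on GC content, per 10 percentage points. In the GC-adjusted fit this slope is a covariate, which leaves 5 residual degrees of freedom. The rule for named genes was applied to that fit unchanged, and list members were ranked by its adjusted p, since those of the fit without the covariate are tied. Further alternatives added then were per-library offsets smooth in GC content and length, the offsets with the covariate, a covariate from the first component of the DMSO libraries, and fits without the 60 µM library or with only the 80 and 100 µM libraries.

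Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, DESeq2 size factors within edgeR, scaling by library totals only, no filter, a filter at 5 CPM, a fold change of at least 2, a block on the number in the sample titles, other forms of the dose term, and leaving out each library in turn. They were applied to the GC-adjusted fit as well. Alternatives written for FPKM or TPM (another pseudocount, quantile normalization) did not apply, since counts were at hand.

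Both fits were tested on simulated data made to have the libraries' GC trends, in which a few of 11723 genes were changed. The GC-adjusted fit recovered 1 of 67 genes changed 1.5-fold, 19 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 4 false calls among 86. The fit without the covariate recovered 0 of these genes. A simulated list of shifted genes passed in both fits (camera adjusted p = 7.64e-08 without and 9.45e-24 with the covariate), and 0 of 20 unshifted lists did. The simulated genes were drawn independently of one another, from the same GC slope model that the GC-adjusted fit uses. The simulation therefore does not show the error rates where genes of a list vary together or the trend has another form. Each pair of the 8 libraries was checked for duplicates, and none was found (chi-square per degree of freedom of at least 29.0, the lowest between 80 and 100 µM).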

Results

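The transcriptome of MHCC-97H hepatocellular carcinoma cells was measured by RNA sequencing after 24 hours with DMSO (4 libraries) or with 40, 60, 80 or 100 µM lenvatinib (1 library per dose). The DMSO libraries held 32306908, 30635814, 31466850 and 34240835 counts. The lenvatinib libraries held 30077668 counts at 40 µM, 10181973 at 60 µM, 37384578 at 80 µM and 34747706 at 100 µM. The 60 µM library had reads for 11076 genes, against 13290 to 14340 genes in the other libraries.

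Libraries differed from one another mainly along an axis that followed the GC content of genes. The first principal component of the log2 values held 84.5% of the variance and followed the libraries' GC slopes (absolute Pearson r = 0.996). With offsets smooth in GC content and length taken out, the first component held 65.4% of the remaining variance. It still followed the GC slopes (absolute Pearson r = 0.976), so offsets from the GC content and length of the longest transcript did not take the axis out. The GC slope, the log2 deviation of a library from the mean of the 8 libraries per 10 percentage points of GC content, was 0.29, -0.51, -1.01 and -0.10 in DMSO libraries 1 to 4, 0.68 at 40 µM, 1.84 at 60 µM, -0.58 at 80 µM and -0.61 at 100 µM. The arms did not differ in it beyond their spread (mean -0.33 ± 0.56 in DMSO and 0.33 ± 1.17 with lenvatinib, SD, n = 4 each; exact two-sided permutation p = 0.429), and 2 lenvatinib libraries lay inside the DMSO range. Pearson correlations of log2 values across genes, which are not independent replicates, ran from 0.582 between DMSO 3 and 60 µM to 0.981 between 80 and 100 µM.

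**Figure D1:**
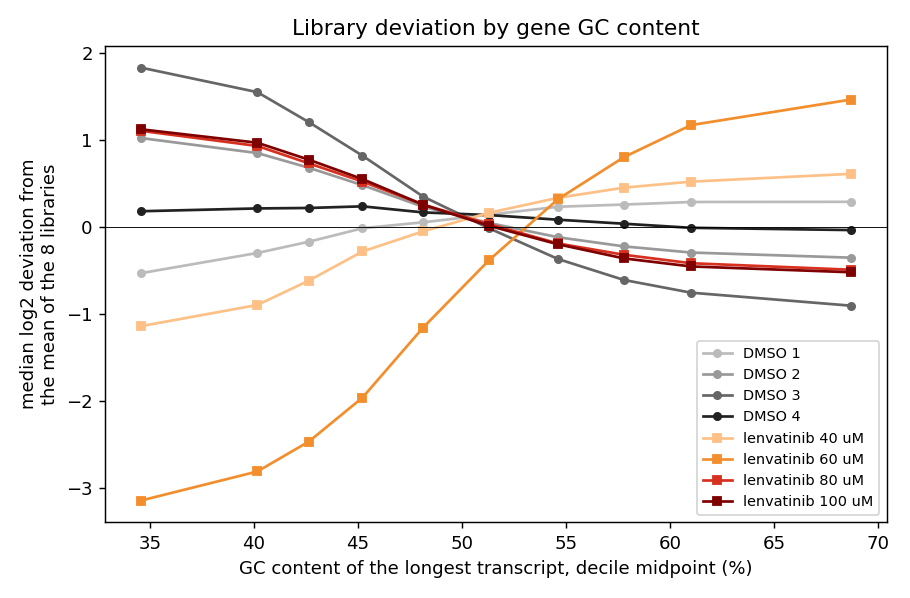
Median log2 deviation of each library from the mean of the 8 libraries (y axis) in 10 equal bins of the tested genes ordered by GC content in percent (x axis), one line per library. The 60 µM library runs from -3.14 in the bin of lowest GC content to 1.47 in the highest, and DMSO 3 runs the other way, from 1.84 to -0.90.

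The comparison of the 4 lenvatinib libraries with the 4 DMSO libraries addresses the question in the series' design, how treated cells differ from their parental counterparts. As groups, NRF2 targets, which serve the antioxidant response, and ATF4 targets, which serve the integrated stress response, were higher with lenvatinib. Genes transcribed in response to ERK activity, hepatocyte genes and a list of genes of the mesenchymal and epithelial state were lower. With an estimated correlation NRF2 targets alone passed, and the adjusted p was 0.175 for ATF4 targets, 0.192 for ERK output, 0.183 for hepatocyte genes and 0.175 for the mesenchymal and epithelial list. Of the 25 NRF2 targets tested, 23 had a positive log2 fold change, with a median of 0.63 (camera adjusted p = 1.36e-08; adjusted p = 0.0262 with an estimated correlation). In all, 12 of 37 gene lists passed in camera, 4 higher and 8 lower, and 8 passed in fry. Without the 80 µM library 6 lists passed, 5 higher and 1 lower, and without the 100 µM library likewise 5 and 1. Of the lower lists, genes of G2 and mitosis alone passed then. The medians of the ERK output, hepatocyte and mesenchymal and epithelial lists, at -0.45, -1.26 and -0.59 with all libraries, were -0.33, -1.19 and -0.83 without 80 µM (camera adjusted p = 0.0862, 0.0862 and 0.0780). They were -0.33, -1.22 and -0.73 without 100 µM (camera adjusted p = 0.0628, 0.0823 and 0.0734). Without DMSO 3 they were -0.49, -1.35 and -0.27, and each list passed (camera adjusted p = 2.79e-04, 8.21e-04 and 0.00461). With a filter at 5 CPM, ERK output (15 members, median -0.24, camera adjusted p = 0.179) and hepatocyte genes (3 members, median -0.16, camera adjusted p = 0.532) did not pass, and the mesenchymal and epithelial list did (16 members, median -0.48, camera adjusted p = 0.0183).

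No single gene was called in this comparison. The edgeR test called 0 of 11827 genes, with 523 at an unadjusted p under 0.05 and a lowest adjusted p of 0.874. DESeq2 called 94 genes, 59 higher and 35 lower, and limma-voom called 0. The 4 lenvatinib libraries all lay above the 4 DMSO libraries for 364 genes and all below for 400, which is 6.46% of the genes tested. Without ties, the average over all splits into 4 and 4 is 2.86%. Genes vary together, so the share in a single split can lie well off this average, and it was not computed for other splits. The median log2 fold change of all genes was -0.11, and -0.20 when libraries were scaled by their totals only.

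With each library's GC slope as a covariate, a fit added after the data had been seen, edgeR called 391 genes, 177 higher and 214 lower with lenvatinib, of which 81 and 122 changed at least 2-fold. Of these genes, 353 had the same sign without the covariate. The count depends on single libraries. It was 0 without the 80 µM library, 9 without 100 µM, 18 without DMSO 4, 26 without DMSO 1, 66 without DMSO 2, 217 without DMSO 3, 1009 without 40 µM and 2770 without 60 µM. The values below are from this GC-adjusted fit unless another is named, and each gene's call is lost without the 80 µM library. There all 387 of these genes that were tested kept their sign. Their median absolute log2 fold change was 0.96 and their median SE 0.21, against 1.02 and 0.17 with all libraries. The genes were chosen in the fit with all libraries, which shares its other libraries with this one, so kept signs are no independent support.

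NRF2 targets had the lowest adjusted p of the lists in camera with the preset correlation. In fry the mesenchymal and epithelial list came first (adjusted p = 6.17e-05, against 0.00399 for NRF2 targets). With the covariate 16 lists passed in camera and 11 in fry. Of 25 tested NRF2 targets 10 rose and 0 fell (15 rose when p-values were adjusted over the list alone). The median log2 fold change was 0.59 (camera adjusted p = 9.27e-13; adjusted p = 0.252 with an estimated correlation). AKR1C1 (ENSG00000187134, GRCh38 chromosome 10, 4963253 to 4983283), an aldo-keto reductase that reduces steroids and reactive carbonyls, rose from 14.2 ± 2.82 CPM in DMSO to 52.8 ± 14.0 CPM with lenvatinib (SD, n = 4 each), a log2 fold change of 1.71 ± 0.17 (SE; edgeR adjusted p = 0.00517). Its neighbour AKR1C2 (ENSG00000151632, chromosome 10, 4987400 to 5017955) rose by 1.41 ± 0.15 on the log2 scale (edgeR adjusted p = 0.00565). Over the alternatives run, the log2 fold changes ranged from 1.62 to 3.72 for AKR1C1 and from 1.31 to 3.76 for AKR1C2. OSGIN1 (ENSG00000140961, chromosome 16, 83948282 to 83966332), an oxidative stress-induced growth inhibitor, rose by 1.53 ± 0.16, from 24.8 ± 11.1 to 119 ± 90.4 CPM, with the highest level, 251 CPM, at 60 µM. GCLM, a subunit of the enzyme that makes the glutathione precursor glutamylcysteine, had a log2 fold change of 0.95 ± 0.11 (edgeR adjusted p = 0.00856), although its levels overlapped between arms (37.5 ± 14.6 against 53.4 ± 36.0 CPM). It reached 89.7 CPM at 80 µM and 77.7 CPM at 100 µM.

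ATF4 targets rose as a list as well, with 4 of 42 tested members higher and 0 lower (12 higher and 1 lower when adjusted over the list alone). The median was 0.32 (camera adjusted p = 6.91e-07; adjusted p = 0.362 with an estimated correlation). In fry the list did not pass (adjusted p = 0.0941), and the 4 called members include ATF4 itself. Without the covariate the list passed in fry (adjusted p = 0.0496). Its median there was 0.41 (camera adjusted p = 2.91e-05; adjusted p = 0.175 with an estimated correlation). That median was 0.27 when the 80 µM library was left out (camera adjusted p = 0.00634). ATF4 (ENSG00000128272, chromosome 22, 39519695 to 39522685), the transcription factor of the integrated stress response, rose from 160 ± 7.97 to 294 ± 49.7 CPM (SD, n = 4 each), by 0.81 ± 0.14 on the log2 scale (edgeR adjusted p = 0.0235). All 4 lenvatinib libraries lay above the DMSO libraries. ASNS (ENSG00000070669, chromosome 7, 97852118 to 97872542), asparagine synthetase, went from 41.5 ± 9.29 to 99.3 ± 37.9 CPM (log2 fold change 1.33 ± 0.28, edgeR adjusted p = 0.0451), a call that was lost without the 60 µM library at about the same fold change (1.35 ± 0.36, adjusted p = 0.0562). NUPR1, a stress-induced chromatin protein, rose by 0.91 ± 0.18, and CBS, the first enzyme of transsulfuration, by 0.68 ± 0.14. DDIT3, the proapoptotic factor CHOP, was not called (4.90 ± 2.33 against 3.55 ± 2.07 CPM; log2 fold change -0.45 without the covariate and 0.02 with it). The ER chaperone list, driven by XBP1 and ATF6, was lower, with a median of -0.29 and 0 of 24 members called (camera adjusted p = 0.0372; adjusted p = 0.795 with an estimated correlation). It did not pass in fry (adjusted p = 0.236), nor in camera without DMSO 1 (median -0.25, camera adjusted p = 0.0651) or 100 µM (-0.26, 0.159). Its camera adjusted p was 0.0496 without the covariate (adjusted p = 0.533 with an estimated correlation), and there it did not pass without DMSO 1 (median -0.46, camera adjusted p = 0.110), 80 µM (-0.56, 0.0882) or 100 µM (-0.54, 0.149).

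Genes transcribed in response to ERK activity fell as a list. Of 24 tested members 6 fell and 0 rose (11 fell when adjusted over the list alone). The median was -0.59 (camera adjusted p = 6.91e-07; adjusted p = 0.331 with an estimated correlation). Without the covariate the median was -0.45 (camera adjusted p = 0.00364; adjusted p = 0.192 with an estimated correlation). DUSP4 (ENSG00000120875, chromosome 8, 29333064 to 29350668), a phosphatase that inactivates MAP kinases, fell from 3.70 ± 1.12 to 0.956 ± 0.645 CPM (log2 fold change -2.73 ± 0.30, edgeR adjusted p = 0.00705). The ETS transcription factor ETV4 (log2 fold change -2.32 ± 0.28), the AP-1 subunit FOSL1 (-1.39 ± 0.22) and the receptor tyrosine kinase EPHA2 (-0.75 ± 0.12) were also called. Their levels overlapped between arms, and without the covariate their log2 fold changes were -0.80, -0.49 and -0.35. ETV4 stood at 36.1 CPM at 60 µM and at 2.47 and 4.10 CPM at 80 and 100 µM, against 26.7 ± 11.7 CPM in DMSO.

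Of 10 receptors listed as targets of lenvatinib, 3 were expressed at a level that was tested, FGFR1, FGFR3 and FGFR4. FLT1, FLT4 and PDGFRA had 0 reads in every library, and KIT and RET had 6 and 4 reads over the 8 libraries. KDR, the main VEGF receptor, and FGF19, the ligand of FGFR4, had 0 reads in every library, which allows up to 3 counts in each. FGFR2 had 240 reads over the 8 libraries and the ERK phosphatase DUSP6 had 94, both under the filter. DUSP6 had 2, 14, 16 and 18 reads in DMSO 1 to 4, 0 at 40 µM and at 60 µM, 23 at 80 µM and 21 at 100 µM. Its raw counts were thus not lower at 80 and 100 µM, and they were neither GC-adjusted nor tested. FGFR1, FGFR3 and FGFR4 were measured at 32.3 ± 8.49, 51.6 ± 5.12 and 58.1 ± 26.3 CPM in DMSO and 36.7 ± 11, 62.3 ± 10.5 and 91.2 ± 76.4 CPM with lenvatinib, and none was called. Their log2 fold changes were 0.18, 0.27 and 0.65 without the covariate and -0.10, 0.15 and -0.31 with it. As a list, these 3 receptors did not pass (camera adjusted p = 0.343 without and 0.737 with the covariate). EGFR was measured at 140 ± 101 against 108 ± 83.8 CPM and was not called.

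Hepatocyte genes, of which 8 of 34 were expressed at a level that was tested, were lower with lenvatinib. With the covariate 4 fell and 0 rose, both over all genes and adjusted over the list alone. The median was -1.49 (camera adjusted p = 0.00509; adjusted p = 0.362 with an estimated correlation). Without it the camera adjusted p was 0.0129 (adjusted p = 0.183 with an estimated correlation), with 0 called and 4 lower when adjusted over the list alone. Only 3 of the 8 pass a filter at 5 CPM, with a median of -0.16 (camera adjusted p = 0.532 without the covariate). HNF4A (ENSG00000101076, chromosome 20, 44355700 to 44434596), the nuclear receptor that maintains hepatocyte identity, fell from 8.42 ± 1.23 to 1.78 ± 1.11 CPM (SD, n = 4 each; log2 fold change -2.42 ± 0.40, edgeR adjusted p = 0.0229). FGB (ENSG00000171564, chromosome 4, 154562956 to 154571086) and FGA, chains of fibrinogen, fell from 5.00 ± 2.65 to 0.286 ± 0.297 CPM and from 2.498 ± 0.747 to 0.287 ± 0.263 CPM (log2 fold changes -3.56 ± 0.33 and -2.70 ± 0.42). RBP4, the plasma retinol carrier, fell by 2.67 on the log2 scale. Albumin (ALB) had 6 reads and alpha-fetoprotein (AFP) 2, so neither was tested. These reads, and those of APOA1 (10), APOA2 (7) and TF (4), all came from the 60 µM library, which stands apart in this. Without that library the hepatocyte list passed with a median of -1.21 (camera adjusted p = 6.38e-04) and, with the covariate, -1.42 (0.0257). The list of hepatic progenitor and liver cancer markers was lower with 1 of 8 members called and 4 lower when adjusted over the list alone (camera adjusted p = 0.0354; adjusted p = 0.331 with an estimated correlation). It did not pass without DMSO 2 (median -0.27, camera adjusted p = 0.0622), DMSO 3 (-0.24, 0.103) or 40 µM (-0.26, 0.245). Its called member was ANPEP, a membrane aminopeptidase, at -2.00 ± 0.21.

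The list of the mesenchymal and epithelial state was lower, with 5 of 20 members lower and 0 higher (10 lower and 2 higher when adjusted over the list alone). The median was -0.57 (camera adjusted p = 0.00334; adjusted p = 0.252 with an estimated correlation). The matrix protein TGFBI fell from 90.2 ± 18.6 to 32.1 ± 14.0 CPM (log2 fold change -1.67 ± 0.28). The integrin ITGA5 (-0.82 ± 0.15) and the cytokine TGFB1 (-0.93 ± 0.14) were called with overlapping levels, and TGFB1 had a log2 fold change of 0.34 without the covariate. The members did not move towards one state. Uncalled epithelial keratins KRT18 and KRT8 had log2 fold changes of -0.93 and -0.87, and the mesenchymal regulators SNAI2 and TWIST1 0.86 and 0.97, also uncalled.

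The naming rule chose 24 genes from the 102 higher and 45 lower genes that met its conditions. SERPINE2 (ENSG00000135919, chromosome 2, 223975112 to 224039319), a protease inhibitor that blocks thrombin and urokinase, fell from 13.0 ± 0.892 to 1.78 ± 0.655 CPM (SD, n = 4 each), by 2.68 ± 0.21 on the log2 scale (edgeR adjusted p = 0.00393). PLAU, which encodes urokinase, the Kunitz-type inhibitor TFPI2, the laminin chain LAMA1 and the transglutaminase TGM2, which cross-links matrix proteins, had log2 fold changes of -2.46, -2.17, -2.25 and -2.66. The other lower genes were the serotonin receptor HTR1D (-3.36), the ion channel CALHM3 (-2.92), C2orf54 (-2.76), cardiac actin ACTC1 (-2.37) and CRYBG2 (-2.36), with HNF4A and RBP4 given above. Among the higher genes, SECTM1 (ENSG00000141574, chromosome 17, 82321024 to 82334074), a secreted and transmembrane protein, rose from 3.24 ± 0.736 to 35.1 ± 29.97 CPM (log2 fold change 2.70 ± 0.24, edgeR adjusted p = 0.00426), and MAFG, a partner of NRF2, from 30.5 ± 18.1 to 114 ± 17.8 CPM (1.94 ± 0.38). The helix-loop-helix factor ATOH8 (1.51 ± 0.10), the metalloproteinase MMP28 (1.85), the calcium sensor KCNIP3 (1.78), the immunoproteasome subunit PSMB9 (1.72), PIGZ (1.63), SRGAP3 (1.55), PCBP3 (4.53) and HID1 (2.73) rose as well, with AKR1C1 and OSGIN1 given above. PCBP3 and HID1 were highest by far at 60 µM (27.8 and 53.1 CPM), and HID1 fell under the filter without that library.

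**Figure D2:**
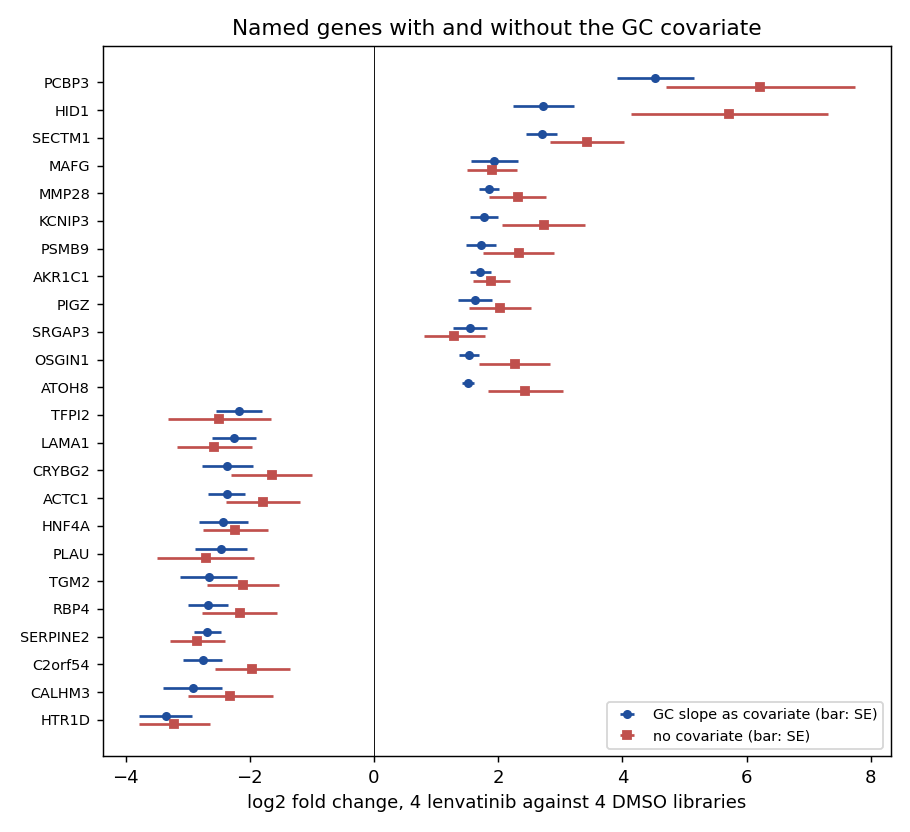
Log2 fold change of lenvatinib against DMSO (x axis; 4 libraries each) for the 24 genes chosen by the naming rule, with the GC slope as covariate (circles) and without it (squares); bars are the SE. Each gene has the same sign in both fits, and the bars are wider without the covariate for genes such as PCBP3 and HID1.

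Interferon-stimulated genes rose as a list, with 3 of 20 members higher and 0 lower (7 higher and 1 lower when adjusted over the list alone). The median was 0.29 (camera adjusted p = 2.23e-04; adjusted p = 0.331 with an estimated correlation). Without the covariate the camera adjusted p was 1.50e-04 (adjusted p = 0.175 with an estimated correlation). The called members were PSMB9 above, HLA-B, an MHC class I chain (45.4 ± 7.12 to 97.8 ± 11 CPM, log2 fold change 1.00 ± 0.13), and IFI6 (15.2 ± 3.78 to 31.5 ± 6.99 CPM, 1.24 ± 0.17).

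Heat shock genes were lower, with 2 of 18 members called (4 when adjusted over the list alone) and all 18 fold changes negative (median -0.45, camera adjusted p = 3.12e-05; adjusted p = 0.362 with an estimated correlation). The called members were the small heat shock protein CRYAB (-2.45 ± 0.37) and the collagen chaperone SERPINH1 (-0.74 ± 0.13). Without the covariate the list's camera adjusted p was 0.0114 (adjusted p = 0.381 with an estimated correlation). All 24 genes of ribosome biogenesis and MYC activity had negative fold changes and 0 were called (median -0.48, camera adjusted p = 2.64e-05; adjusted p = 0.424 with an estimated correlation). Without the covariate the camera adjusted p was 0.0115 (adjusted p = 0.401 with an estimated correlation). In fry this list passed neither with the covariate (adjusted p = 0.0823) nor without it (adjusted p = 0.0814). Genes of G2 and mitosis were lower with 1 of 36 called (median -0.30, camera adjusted p = 0.0381; adjusted p = 0.331 with an estimated correlation). That list did not pass without DMSO 2 (median -0.30, camera adjusted p = 0.0624), DMSO 3 (-0.31, 0.0621), 40 µM (-0.32, 0.175) or 100 µM (-0.28, 0.0524). Without the covariate the camera adjusted p was 0.0129 (adjusted p = 0.682 with an estimated correlation). The called member, the mitotic kinesin CENPE (-1.55 ± 0.27), spread widely in DMSO, from 0.217 to 23.6 CPM. The proliferation marker MKI67 was measured at 69.3 ± 67.0 against 28.8 ± 22.2 CPM and was not called. Nor was the CDK inhibitor CDKN1A, at 116 ± 61.5 against 171 ± 158 CPM. Replication-dependent histone genes were higher without the covariate (median 0.97, camera adjusted p = 0.0124; adjusted p = 0.527 with an estimated correlation) but not with it (median 0.02, camera adjusted p = 0.563).

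Of the metabolic lists, cholesterol synthesis genes were lower in the GC-adjusted fit with 2 of 27 called (8 lower when adjusted over the list alone). Their median was -0.24 (camera adjusted p = 0.0354; adjusted p = 0.424 with an estimated correlation), and the list did not pass without the covariate (camera adjusted p = 0.850). Nor did it pass with the covariate but without DMSO 2 (median -0.19, camera adjusted p = 0.0624), 40 µM (-0.24, 0.171) or 100 µM (-0.23, 0.0923). The called members were the sterol reductase DHCR7 (-0.52 ± 0.10) and squalene synthase FDFT1 (-0.69 ± 0.14). DHCR7 had a log2 fold change of 0.43 without the covariate, and both values were positive or at 0 with the GC and length offset (0.00 and 0.11). HMGCS1, a HMG-CoA synthase of this pathway, was measured at 32.5 ± 23.5 against 13.5 ± 11.7 CPM and was not called. Hypoxia and glycolysis genes were lower with 3 of 34 called, also when adjusted over the list alone, and did not pass in fry (adjusted p = 0.167). Their median was -0.33 (camera adjusted p = 0.00907; adjusted p = 0.793 with an estimated correlation), and the list did not pass without the covariate (camera adjusted p = 0.572). Those were carbonic anhydrase CA9 (1.75 ± 1.10 to 0.424 ± 0.792 CPM, with 0 reads at 80 and 100 µM), the glucose transporter SLC2A1 (-0.59 ± 0.12) and NDRG1 (-0.68 ± 0.15). Ferroptosis regulators were higher with 1 of 22 called, GCLM (5 when adjusted over the list alone). This list is not independent of those above. It shares GCLM, GCLC, SLC7A11, HMOX1, FTL and FTH1 with the NRF2 targets, and CHAC1, SLC7A11 and SLC3A2 with the ATF4 targets. The camera adjusted p was 0.0218 (adjusted p = 0.362 with an estimated correlation), and 0.182 without the covariate. In fry the ferroptosis list did not pass with the covariate (adjusted p = 0.0644). FOXO targets had 0 of 15 called, with a median of 0.22 (camera adjusted p = 0.0405; adjusted p = 0.331 with an estimated correlation), where the median without the covariate was -0.22 (camera adjusted p = 0.711). With the covariate they did not pass without DMSO 1 (median 0.14, camera adjusted p = 0.106), DMSO 4 (0.16, 0.0621), 60 µM (0.18, 0.0616) or 80 µM (0.25, 0.108), nor with the 80 and 100 µM libraries only (0.13, 0.0682).

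**Figure D3:**
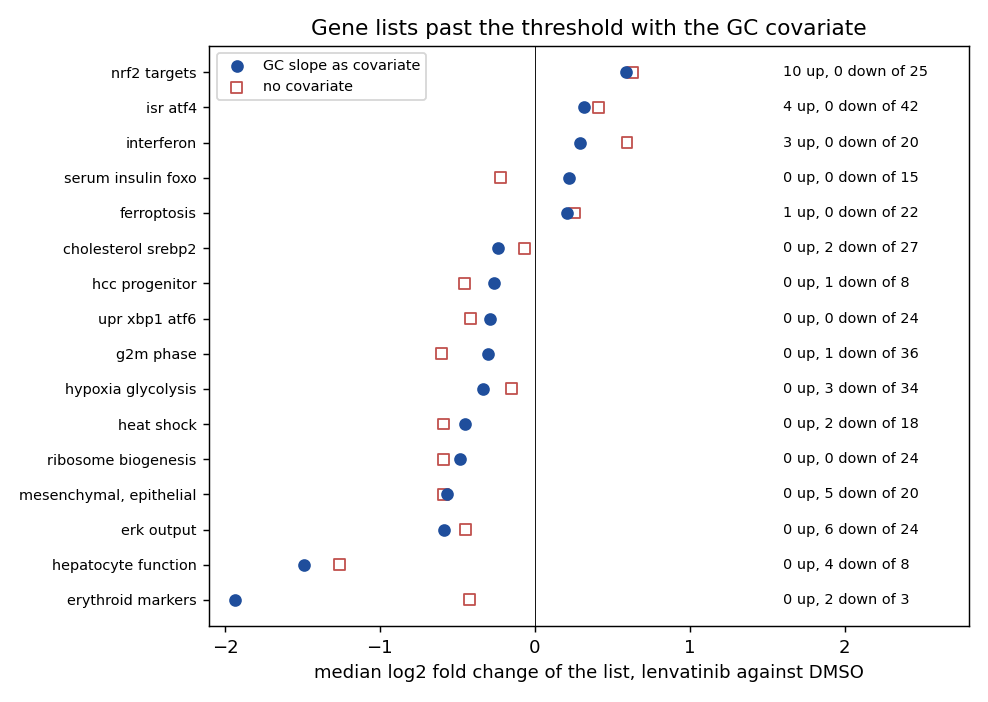
Median log2 fold change of lenvatinib against DMSO (x axis) for the 16 lists past the threshold in camera with the GC slope as covariate (circles), with the value without it (squares); text on the right counts called members. NRF2 targets lie at 0.59 and 0.63, and FOXO targets change sign between the fits.

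Markers of other cell types were tested as well. Of 3 erythroid markers tested, HBA1 (11.2 ± 7.34 to 8.23 ± 8.16 CPM) and HBA2 (8.37 ± 5.53 to 6.32 ± 6.47 CPM), near-identical alpha-globin genes, were called lower with the covariate (log2 fold changes -1.94 ± 0.27 and -1.93 ± 0.26). The list's camera adjusted p was 0.00869 (adjusted p = 0.331 with an estimated correlation), and 0.862 without the covariate. The 4 fibroblast markers tested held 0 calls (camera adjusted p = 0.737). Of the leucocyte markers 2 were tested and both were called lower, the CSF1 receptor CSF1R (-3.12 ± 0.58) and the lysosomal protein CD68 (-1.19 ± 0.20). Of the endothelial markers 2 were tested and neither was called: ESAM (65.5 ± 21.3 to 56.5 ± 29.6 CPM, log2 fold change -0.77 ± 0.17, edgeR adjusted p = 0.0506) and VWF (-0.80 ± 0.89, edgeR adjusted p = 0.664). Without the 60 µM library ESAM passed (-0.71, edgeR adjusted p = 6.37e-04). The leucocyte marker LYZ had 4 reads, all at 60 µM. PTPRC, the common leucocyte antigen, had 0 reads in every library, which allows up to 3 counts in each.

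**Figure D4:**
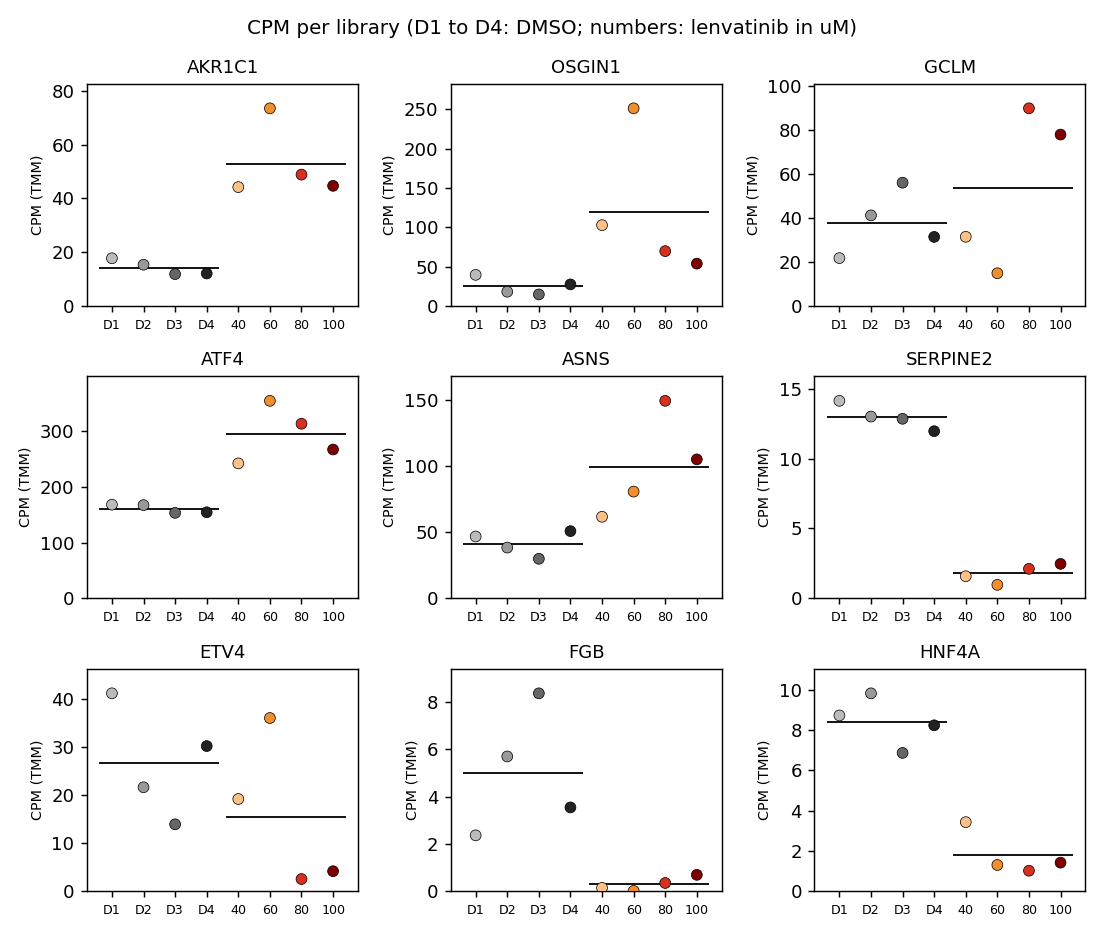
TMM-scaled CPM (y axis) in each library (x axis: DMSO 1 to 4, then lenvatinib by dose in µM) for 9 genes named in the text; points are libraries and horizontal lines the means of each arm. ATF4 lies at 242 to 354 CPM with lenvatinib and at 153 to 168 CPM in DMSO, and ETV4 at 60 µM lies within the DMSO range.

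The dose slope asks for a change with dose beyond the mean difference from DMSO. Among named genes, ASNS had a slope of 0.34 per 20 µM on the log2 scale (edgeR adjusted p = 0.295), ATF4 0.02 and AKR1C1 -0.07, and none passed. The edgeR test called 0 genes, with 875 at an unadjusted p under 0.05 and a lowest adjusted p of 0.295. DESeq2 called 131 (113 with a positive slope and 18 with a negative one) and limma-voom 0. With the GC covariate edgeR called 0, with 284 at an unadjusted p under 0.05. Of the lists, cytosolic ribosomal proteins (median slope -0.45, camera adjusted p = 4.22e-05) and nuclear-encoded respiratory chain subunits (-0.23, camera adjusted p = 0.0132) had negative slopes, each with an adjusted p = 0.887 with an estimated correlation. Without the 100 µM library 4 lists passed. With the GC covariate neither of the pair passed (camera adjusted p = 0.2504 and 0.242). ATF4 targets alone did, upwards (median 0.04, camera adjusted p = 0.0186; adjusted p = 0.955 with an estimated correlation).

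Each dose was set against DMSO as a description only, since with 1 library per dose the spread comes from the DMSO libraries alone. They reach a GC slope of 0.29, so the covariate is extrapolated to 0.68 at 40 µM and 1.84 at 60 µM. With the GC covariate SECTM1 had log2 fold changes of 2.18 ± 0.22 at 40 µM, 3.34 ± 0.37 at 60 µM, 2.88 ± 0.14 at 80 µM and 2.63 ± 0.15 at 100 µM (SE). SERPINE2 stood at -3.10 ± 0.30, -3.88 ± 0.53, -2.60 ± 0.24 and -2.37 ± 0.24. ASNS stood at 0.03 ± 0.20, -0.23 ± 0.34, 2.01 ± 0.14 and 1.52 ± 0.14. The difference between these doses was not tested beyond the dose slope above. NUPR1 stood at 0.23 ± 0.16, 0.66 ± 0.26, 1.16 ± 0.11 and 1.01 ± 0.11.

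Without the covariate edgeR called 0 genes at 40, 80 and 100 µM (1019, 336 and 261 at an unadjusted p under 0.05; DESeq2 668, 38 and 30; limma-voom 0 at each) and 4403 at 60 µM, 1406 higher and 2997 lower. The 60 µM count was 0 without DMSO 2 and 0 without DMSO 4, 6708 without DMSO 1, 7170 in DESeq2 and 13 in limma-voom. The median log2 fold change of all genes there was -0.74 (-1.57 with library totals only). With the covariate 43 genes were higher and 168 lower at 40 µM, 697 and 3404 at 60 µM, 501 and 849 at 80 µM, and 248 and 486 at 100 µM.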

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

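The tests of whether treatment orders the GC slopes, of the calls without GC adjustment against other splits, of a smooth trend in GC content or length, of the 60 µM library alone and of an exchange between DMSO 3 and 40 µM were chosen after the result was seen, as was the GC-adjusted fit itself.

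In 4 of 64 groups of 4 DMSO values tested, 1 library lay far from the other 3, where chance gives about 1 in 20. PCBP3 stood at 0.362 CPM in DMSO 1, against 0 to 0.0595 CPM in the others. MAFG stood at 57.6 CPM in DMSO 2, against 20.6 to 22.9 CPM. PIGZ stood at 1.57 CPM in DMSO 2, against 2.64 to 2.79 CPM. CENPE stood at 23.6 CPM in DMSO 3, against 0.217 to 3.62 CPM.

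The libraries spread along the GC content of genes, with slopes from -1.01 in DMSO 3 to 1.84 at 60 µM. Lenvatinib treatment as the whole cause is argued against by the DMSO libraries, which alone span 45.6% of the full range, with 2 lenvatinib libraries inside it. Depth and gene length are argued against too: thinning the other libraries to the total of the 60 µM library moved no slope towards it by more than 0.048, and within 5 bins of transcript length its slope kept at least 79.5% of the overall value. With offsets smooth in GC content and length taken out, the first principal component still followed the slopes (absolute Pearson r = 0.976). A GC bias of library preparation or amplification may account for the spread or a part of it and stays open, as no label gives a batch and it was not tested. A contribution of treatment at 60 µM, where the slope is highest and the depth lowest, cannot be separated from it with 1 library.

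The 391 genes called with the GC covariate form the second pattern, and among the 35 splits of the 8 libraries into 4 and 4, 2 gave as many calls, so chance cannot be excluded for the count; the highest other split gave 1958 and exchanges DMSO 3 with 40 µM, which points to a structure of the samples. The median GC content of higher and lower calls differed by -0.547 percentage points, which decides nothing, as the covariate removes a linear trend from the fold changes by construction, but a leftover trend smooth in GC content or length is argued against by 384 of the calls being made with the same sign when offsets for it were added to the covariate, and the 60 µM library alone by 386 being made from the 80 and 100 µM libraries. For an exchange of DMSO 3 and 40 µM, 100 genes were chosen without either library. Of these, 84 differed between them in the direction of treatment once the GC slope was removed (50 before). With the slope removed, 90 placed DMSO 3 with DMSO and 64 placed 40 µM with lenvatinib. Each gene's slope came from libraries with GC slopes of -0.61 to 0.29 and was extrapolated to -1.01 in DMSO 3 and 0.68 at 40 µM. The values go against an exchange only if that extrapolation holds, so it is not excluded. A response to lenvatinib may underlie these calls, but differences between cultures or preparations stay open, as no label gives them, and so does a link of being called with GC content, since higher and lower calls alike lie above the median of all tested genes (57.5% and 58.05% against 49.7%).

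The third pattern is the group change of NRF2 targets (higher), ATF4 targets (higher) and ERK output genes (lower). In the GC-adjusted fit, the GC content and expression level of the list's genes are argued against for each. Among 10000 random lists matched on both, the medians lay at percentile 100 for NRF2 targets, 100 for ATF4 targets and 0 for ERK output genes. The covariate had removed a linear GC trend from these fold changes, so for GC content this covers only what was left. No matched lists were drawn for the fit without the covariate. For the number of lists past the threshold, 1 of the 35 splits, the real one, gave as many in both fits. It gave 12 lists against at most 10 without the covariate, and 16 against at most 15 with it. This met the limit set beforehand but does not exclude chance, as 1 of 35 is the lowest share possible and the margins are small. The 12 lists become 6 without the 80 µM or the 100 µM library. With the covariate ATF4 targets did not pass in fry (adjusted p = 0.0941). An oxidative and amino acid stress response with lower ERK output under lenvatinib is a hypothesis only, which these counts do not decide and separate cultures at each dose would test. Correlation between the genes of a list stays open, since with an estimated correlation only NRF2 targets passed without the covariate and no list passed with it, and a shared difference in culture or handling between the arms was not tested.

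In 2 fits that lost most of these calls, the fold changes were about as large and their SE wider. The genes had been chosen for their calls in the fit with all libraries, so kept signs and sizes are largely given by that choice. Without the 80 µM library 0 of the 391 genes were called, and all 387 tested there kept their sign (median absolute log2 fold change 0.96 and median SE 0.21, against 1.02 and 0.17). With the offsets alone 33 were called and 381 kept their sign (0.93 and 0.28).

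Without GC adjustment, where edgeR called 0 genes (523 at an unadjusted p under 0.05, DESeq2 94, limma-voom 0), the 35 splits decide nothing about chance, as none can give fewer. The highest other, 4868, parts the libraries by their GC slopes (DMSO 1 and 4 with 40 and 60 µM).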

How the results depend on the processing

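The GC-adjusted fit and its alternatives were added after the data had been seen. The 0 calls of edgeR for all doses against DMSO (523 at an unadjusted p under 0.05) held in limma-voom, with DESeq2 size factors, library totals, no filter, a filter at 5 CPM, a 2-fold minimum, a replicate block on the number in the titles, and without each library (0 to 0). DESeq2 gave 94, the GC covariate 391, the DMSO component covariate 458, the GC and length offset 33, both together 1219, the covariate without 60 µM 2770 and with 80 and 100 µM only 2470. The labels do not say whether libraries of the same number in the titles were handled together. Deviations from the arm means correlated at 0.627, -0.464, 0.843 and -0.608 between libraries of the same number. Of these, 0 of 4 were closest to their own number. The deviations were not adjusted for the GC slopes, which dominate them, so this check cannot decide whether the numbers are a pairing.

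The 391 calls became 0 without the covariate, 2054 in DESeq2, 835 in limma-voom, 1011 with DESeq2 size factors, 621 with library totals (380 higher and 241 lower), 203 with a 2-fold minimum and 227 with the replicate block, and stayed at 280 with no filter and 478 at 5 CPM. Leaving out 1 library gave 0 to 2770. List counts with an estimated correlation were 1 of 12, 0 of 16 with the covariate and 0 of 2 for the dose slope (fry 0); the slope lists numbered 1 with the covariate and 2 to 4 without 1 library, and the lists for all doses 6 to 13, or 13 to 15 with the covariate. The dose slope stayed at 0 calls except in DESeq2 (131), with the GC covariate, log2 dose, a line through all libraries and the lenvatinib libraries alone among the others; a replicate block is not possible there, as number and dose coincide. Against DMSO, DESeq2 gave 668, 7170, 38 and 30 at 40, 60, 80 and 100 µM, the covariate 211, 4101, 1350 and 734, limma-voom 13 at 60 µM, and leaving out a DMSO library 0 to 6708 there. For all of these the cause was not tested.

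Of 52 genes named in the GC-adjusted fit, 49 kept their sign under every alternative run, the fit without the covariate included. Of 1022 values 689 kept sign and side of the threshold, 329 lost the call and 4 reversed: DHCR7 (0.0035) and FDFT1 (0.11) with the GC and length offset, and DHCR7 (0.43) and TGFB1 (0.34) without the covariate. In the fit without the covariate, 27 of 209 values of uncalled genes reversed. With library totals FGFR1 went to -0.011. With the GC covariate FGFR1, FGFR4, CDKN1A, DDIT3 and EGFR went to -0.10, -0.31, -0.54, 0.016 and 0.29. With the DMSO component covariate FGFR1, FGFR4, CDKN1A and EGFR went to -0.086, -0.26, -0.48 and 0.24. With the offset FGFR3 went to -0.062. With both, FGFR1, FGFR4, CDKN1A, DDIT3 and EGFR went to -0.081, -0.27, -0.46, 0.14 and 0.33. With the covariate and no 60 µM library, in the same order, they went to -0.040, -0.28, -0.52, 0.034 and 0.27. With 80 and 100 µM only FGFR4, CDKN1A and EGFR went to -0.24, -0.55 and 0.18. Leaving out 1 library gave -0.25 to 0.91 for CDKN1A, -0.74 to 0.25 for EGFR and -0.061 to 0.98 for FGFR4. The cause was not tested. Depth limits the 60 µM library most, where 3 counts are 0.295 CPM against 0.0802 to 0.0997 CPM elsewhere.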

Other observations

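The TGF-beta list below was written after genes such as TGFBI, SERPINE2 and TGFB1 had been seen to be lower with the GC covariate, but its test was chosen before its own result was seen.

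Some lists that did not pass held called members. In the GC-adjusted fit NFKBIA, the inhibitor of NF-kappaB, rose from 30.9 ± 6.31 to 61.9 ± 3.32 CPM (SD, n = 4 each; log2 fold change 1.03 ± 0.17, edgeR adjusted p = 0.0221) with all 4 lenvatinib libraries above DMSO, while lipocalin LCN2, of the same list, had a log2 fold change of -1.88 ± 0.28 (edgeR adjusted p = 0.0161; levels overlapped). The transcription factor E2F1, which drives entry into S phase, was called higher (log2 fold change 0.56 ± 0.11, edgeR adjusted p = 0.0354), and it was the only called gene of 36 in the S phase list. Of 13 mRNAs of the mitochondrial genome, MT-ND3 alone was called, lower (-1.02 ± 0.14, edgeR adjusted p = 0.0151), and the share of mitochondrial mRNA in all counts did not differ between arms (difference -0.173 percentage points, exact permutation p = 0.400). AHRR and NQO1, both induced by the aryl hydrocarbon receptor, were called higher (0.80 ± 0.13 and 0.64 ± 0.12), and that list as a whole did not pass (camera adjusted p = 0.164). NQO1 is also among the called NRF2 targets counted above. Each of these calls is lost without the 80 µM library, where 0 genes were called, and the genes were singled out after their values were seen.

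Lower values of genes such as TGFBI, TGFB1 and SERPINE2 raised the hypothesis that TGF-beta target genes are lower with lenvatinib. A list of 34 other TGF-beta targets, 30 of them tested, was compared with the other genes in the GC-adjusted fit. It did not pass over 38 lists (camera adjusted p = 0.489, median -0.09, 13 members higher and 17 lower). In it 1 gene, TAGLN, was called lower, and 1 was higher and 7 were lower when adjusted over the list alone. The list shares genes such as FN1, TAGLN, CDH2 and SNAI2 with lists tested before. The test gives no ground for a general fall of TGF-beta targets.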
